A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

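Transcript levels of budding yeast were measured by single-colour hybridisation (Cy3) of total RNA on Agilent expression arrays, 16 arrays on 4 slides over 2 days. Per the labels, cells were of W303 background and mating type alpha, and were grown in selective synthetic complete medium. Per the file headers, the deposited intensity values were made by Feature Extraction as background-subtracted and spatially detrended spot signals (the processed signal), with the raw median intensities of each spot and of its local background beside them and no normalisation between arrays. The other deposited columns are, per the file headers, 0 or 1 marks per spot for signals well above background, saturation and non-uniform spots. A note from the authors on a further procedure came with the files, and that procedure was run as an alternative.

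Each array held 6256 gene probes with 7 spots each and 1 probe per gene, and 0 spots were saturated. Of the gene names, 5756 were matched to a symbol and 500 kept their systematic name. Signals under 1 were set to 1, log2 values of the 7 spots were averaged, and the array's 75th percentile was subtracted. Genes well above background on at least 3 arrays were kept (6115), and 141 were left out. The dimmest signal called well above background lay between 5.77 and 44.9 units by array, and a gene not well above background on any array of a group was given a bound against that level in place of a fold. Probe positions and sequences were not analysed here.

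The model was fitted with limma 3.58.1 in R 4.3.3 on 15 arrays with group and day as terms and 9 residual degrees of freedom. The tunicamycin array has no replicate and stayed outside the model. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The 4 comparisons with WT and 6 direct contrasts came from the same fit, since comparisons with WT share the WT arrays. The model, the comparisons, the naming rule, 35 gene lists and all alternatives except those said to be added were chosen before the data were examined. The naming rule took the deleted genes, KAR2, HAC1, ERO1, INO1 and OPI1, and the 6 highest and 6 lowest called genes in each comparison with WT (4 and 4 in a direct contrast) whose 3 arrays all lay on the same side of the other group. It left out the deleted genes and strain marker genes from these, and took up to 4 called members with the largest change from each list described. Lists were tested with camera (preset correlation 0.01), adjusted over 140 tests, and repeated with an estimated correlation and with fry, whose p asks whether a list's genes move on balance one way. The gene deleted in a strain was left out of its lists there. With the preset correlation 18 lists passed for DTT, 13 for Δcho2, 14 for Δopi3 and 7 for the arrays labelled Δpah1, with the estimated correlation 0 did, and fry called 32, 28, 28 and 2.

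On simulated data with the same design, 56% to 70% of genes changed by 0.32 on the log2 scale were called, 88% to 96% at 0.58 and 98% to 100% at 2, and 0.07% to 0.24% of unchanged genes were called. The simulated arrays had independent errors, 1 day effect for all groups and no slide effect. These shares thus hold under the model's own assumptions and do not give the rate of false calls in the real arrays. The median standard error of a contrast was 0.068 to 0.070. The day term called 3228 genes, 30 of them at least 2-fold. Arrays were treated as separate cultures, as RNA came from independent samples per the labels. Same-numbered arrays of WT and the deletion strains deviated together (correlations of 0.198 to 0.687), which the shared day of replicate 1 brings about in part. Number 2 correlated best with its own number in 6 of 10 pairs of groups and number 3 in 9 of 10, so a pairing beyond the day is not excluded, and the replicate number was used as a block in an alternative. Overlaps were set against 50 simulations in which unchanged groups shared the WT arrays, again with independent errors and no slide effect. The tunicamycin array was compared with the WT arrays of its own slide, and its list medians with 10000 random lists of like expression.

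Alternatives were normexp background correction (offset 50), quantile normalisation, median centring, no filter and a stricter filter, no day term, the slide as a fixed or random block, day 2 alone, the replicate number as a block, only the groups compared, a fold of at least 1.5, and each of 15 arrays left out. Added after seeing the data were a fit without the pair of arrays labelled Δpah1 with PAH1 at the WT level, and the procedure in the authors' note. Random blocks used statmod 1.5.0, and figures were drawn with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.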

Results

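Budding yeast (Saccharomyces cerevisiae, strain background W303) was grown at 30 °C to an OD600 of 0.25, and transcript levels were measured on 16 single-colour microarrays, each hybridised with total RNA of 1 culture. The groups were untreated wild type (WT, n = 3), the deletion strains Δcho2, Δopi3 and Δpah1 (n = 3 each), WT treated for 1 h with 2 mM dithiothreitol (DTT, n = 3) and WT treated for 1 h with 1 µg/ml tunicamycin (n = 1). CHO2 and OPI3 encode the methyltransferases that turn phosphatidylethanolamine into phosphatidylcholine, and PAH1 encodes phosphatidate phosphatase. DTT and tunicamycin disturb protein folding in the endoplasmic reticulum (ER) and were used, per the labels, to induce the unfolded protein response. Each array held 7 spots for each of 6256 genes, and the 75th percentile of gene signals lay between 6619 and 9779 units. Between 91.1% and 98.4% of genes were well above background on an array. After genes seen on fewer than 3 arrays were left out, 6115 were tested. Errors given with ± are standard errors of the model (n = 3 arrays in each group), and the number of arrays limits their precision. The model pools the spread of all 15 arrays and takes 1 day effect for all groups. They are therefore not the spread of the 2 groups compared. A group that departs from the shared day effect, as the arrays labelled Δpah1 did for INO1 (below), widens the errors of the other contrasts too. Such a group also moves the pooled values of contrasts with DTT, whose arrays are all of day 2 and are set against the other groups through that day effect. Replicate 1 of WT and of each deletion strain was run on day 1 and all other arrays on day 2. Values within each day therefore stand beside most pooled values of the marker genes and list medians where the deletion strains are compared with WT. Most other genes are given as pooled values only. Centring each array on its median in place of its 75th percentile moved the median of all genes by -0.13 in DTT and Δcho2 and by -0.07 in Δopi3, and changes of that size depend on the scaling. Single genes could move further under quantile normalisation. In Δcho2, for example, the mitochondrial genes COX1 and COX3 went from -0.19 to -0.81 and from 0.24 to -0.41.

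The deleted genes were read first. CHO2 (YGR157W) stood at 0.00791%, 0.0252% and 0.0274% of its WT mean on the 3 Δcho2 arrays, not well above background on any of them, which is at least 1748-fold lower than in WT (adjusted p = 1.12e-10). OPI3 (YJR073C) stood at 7.22%, 0.727% and 1.35% on the 3 Δopi3 arrays, a log2 fold change of -5.69 ± 0.56 (adjusted p = 1.66e-06), with -3.57 on day 1 and -6.76 on day 2. It was still well above background on all 3 (7891, 690 and 1500 units), and the source of that signal was not tested. PAH1 (YMR165C) stood at 13.5% on replicate 1 of the arrays labelled Δpah1, still well above background (929 units, a signal whose source was not tested). On replicates 2 and 3 it stood at 98.7% and 93.2%. Its log2 difference from WT was -3.01 on day 1 and 0.01 on day 2, and it did not pass the test (adjusted p = 0.248). On the 13 arrays of other groups PAH1 lay between 93.3% and 144% of its WT mean, CHO2 between 63.2% and 157% and OPI3 between 86.0% and 246%. The label Δpah1 is therefore carried below as the arrays' label only.

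**Figure D1:**
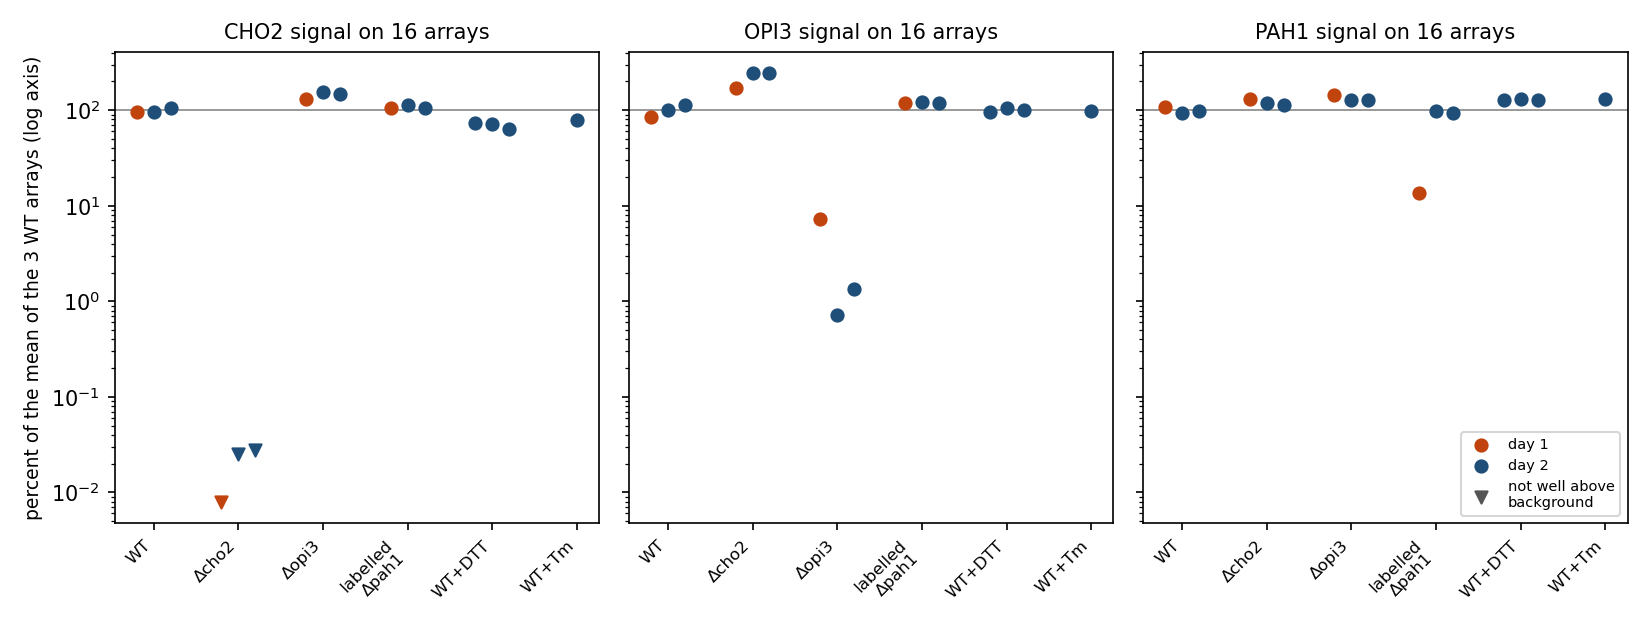
Signal of CHO2, OPI3 and PAH1 on each of the 16 arrays, as percent of the mean of the 3 WT arrays (log axis), coloured by day, with triangles for signals not well above background. CHO2 and OPI3 were low on all 3 arrays of their own deletion strain, OPI3 still well above background there. PAH1 was low, though still well above background, on 1 of 3 arrays labelled Δpah1 (13.5%) and near WT on the others (98.7% and 93.2%).

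The DTT comparison shows which transcripts change in WT cells after 1 h with a reducing agent. ER folding genes were much higher after DTT. KAR2 (YJL034W), the main ER Hsp70 chaperone, rose by 1.49 ± 0.10 on the log2 scale (adjusted p = 5.08e-08). HAC1 (YFL031W), which encodes the transcription factor of the unfolded protein response, rose by 1.61 ± 0.11 (adjusted p = 7.79e-08), and ERO1 (YML130C), the ER thiol oxidase, rose by 2.64 ± 0.12 (adjusted p = 2.30e-09). INO1 (YJL153C), the enzyme that makes inositol phosphate, rose by 3.09 ± 0.53 (adjusted p = 1.76e-04). OPI1 (YHL020C), a repressor of INO1, fell by 0.25 ± 0.10 on the log2 scale (adjusted p = 0.0350). DTT arrays exist for day 2 alone, and against the WT arrays of that day the differences were 1.54 for KAR2, 1.64 for HAC1, 2.66 for ERO1 and 2.90 for INO1.

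Among the 16 genes of ER chaperones and folding, 13 rose and 3 were not called after DTT, with a median log2 change of 1.498 (camera adjusted p = 1.45e-05, adjusted p = 0.628 with an estimated correlation). SIL1 rose 9.27-fold, EUG1 6.93-fold and MPD1 5.97-fold. In ER-associated degradation 15 of 18 genes rose and 1 fell, led by DER1 (4.55-fold), HRD1 (3.39-fold) and DFM1 (3.05-fold), at a camera adjusted p of 2.37e-04 (adjusted p = 0.628 with an estimated correlation). Transport between ER and Golgi moved the same way, with 26 of 30 genes higher, 3 lower and ERV29 2.94-fold and SFB2 2.87-fold higher (camera adjusted p = 1.59e-05, adjusted p = 0.628 with an estimated correlation). Of 35 proteasome genes 32 rose and 3 were not called, with UBI4, the polyubiquitin gene, 2.22-fold and RPT3 1.47-fold higher (camera adjusted p = 1.30e-04, adjusted p = 0.628 with an estimated correlation). In N-glycosylation 18 of 25 genes rose and 1 fell (SEC59 2.67-fold and ALG6 2.38-fold higher), and in O-mannosylation 5 of 6 rose and 1 fell (PMT3 4.91-fold and PMT5 3.09-fold higher). Camera adjusted p was 0.00157 for the first list and 0.0472 for the second (adjusted p = 0.628 with an estimated correlation for both). Adjusted over the list alone, 13 ER chaperone genes, 16 ER-associated degradation genes, 26 transport genes, 33 proteasome genes, 18 N-glycosylation genes and 5 O-mannosylation genes rose.

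Outside the ER, 16 of 20 iron regulon genes rose and 4 were not called (camera adjusted p = 0.00165, adjusted p = 0.628 with an estimated correlation). TIS11, which encodes an mRNA-binding protein of the iron response, rose 42.2-fold, the largest increase in this comparison by the naming rule, and FRE1, a ferric reductase, rose 3.49-fold. Vacuolar proteases and autophagy genes were higher in 15 of 17 cases and lower in 1, with PRB1 3.05-fold and ATG14 2.67-fold higher (camera adjusted p = 0.00568, adjusted p = 0.628 with an estimated correlation). In peroxisome and beta-oxidation 13 of 17 genes rose and 1 fell, with SPS19 2.37-fold higher (camera adjusted p = 0.0472, adjusted p = 0.628 with an estimated correlation). The general stress list had 19 of 24 genes higher and 4 lower, with DDR2 3.83-fold and ALD3 2.75-fold higher and GPH1, glycogen phosphorylase, 2.82-fold lower (camera adjusted p = 0.0496, adjusted p = 0.790 with an estimated correlation). In these lists 16 iron, 15 vacuolar, 14 peroxisomal and 19 general stress genes rose when adjusted over the list alone.

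Growth and respiration genes were lower after DTT. Of 132 ribosomal protein genes 131 fell and 1 rose, with a median of -0.96, RPL8A 7.96-fold and RPL7B 6.90-fold lower (camera adjusted p = 2.03e-28, adjusted p = 0.628 with an estimated correlation). All 34 ribosome biogenesis genes fell, among them DBP2 (2.38-fold) and NSR1 (2.37-fold), and all 10 histone genes fell, HHT1 2.22-fold. Camera adjusted p was 1.37e-09 and 1.97e-04 for these lists (adjusted p = 0.628 with an estimated correlation for both). Of 32 respiratory chain and ATP synthase genes 30 fell and 2 were not called, with CYC1, cytochrome c, 2.88-fold lower (camera adjusted p = 1.58e-08, adjusted p = 0.628 with an estimated correlation). Of 30 amino acid synthesis genes 27 fell, ARG3 6.54-fold and HIS4 2.81-fold (camera adjusted p = 5.24e-08, adjusted p = 0.628 with an estimated correlation). In sulfur amino acid metabolism 19 of 28 genes fell and 1 rose, with MET10 2.51-fold lower (camera adjusted p = 0.00103, adjusted p = 0.713 with an estimated correlation). Of 7 a-cell markers 6 fell and 1 was not called, MFA2 2.98-fold and STE2 2.48-fold (camera adjusted p = 0.0145, adjusted p = 0.628 with an estimated correlation). Of 5 alpha-cell markers 3 rose and 1 fell, a list that did not pass camera (adjusted p = 0.743), with STE3 2.39-fold higher. Glycolysis and fermentation had 16 of 17 genes lower (PFK1 1.64-fold) and a median of -0.37, which turned to 0.095 under quantile normalisation (camera adjusted p = 6.55e-04, adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 131 ribosomal protein, 34 biogenesis, 10 histone, 31 respiratory, 27 amino acid, 19 sulfur, 6 a-cell and 16 glycolysis genes fell.

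By the naming rule, the highest after TIS11 were ULI1 (32.5-fold), RTA1 (28.3-fold), YOL037C (log2 4.70), YJL152W (21.4-fold, well above background on 2 of 3 WT arrays) and YLR349W (18.9-fold). The lowest were the cell wall gene HPF1 (12.1-fold), CSS1 (11.4-fold), YER053C-A (9.25-fold), the hexose transporter gene HXT7 (8.64-fold), the acid phosphatase gene PHO3 (8.63-fold) and YBL029W (8.10-fold). In all, limma called 4713 of 6115 genes, 2580 higher and 2133 lower, and 780 of these differed at least 2-fold (465 higher and 315 lower). The share higher was 54.7% and fell to 44.1% when arrays were centred on their median, so the balance of higher and lower genes turned with the scaling. The 3 DTT arrays all lay on the same side of the 3 WT arrays for 78.0% of genes, against 10% by chance. The list calls of general stress, O-mannosylation, peroxisome, glycolysis, sulfur amino acid metabolism and a-cell markers ended under at least 1 alternative setting.

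In Δcho2, which lacks the first methyltransferase of phosphatidylcholine synthesis, the largest change beside the loss of CHO2 itself was INO1, 181-fold higher (log2 7.50 ± 0.51, adjusted p = 1.03e-07, with 7.18 on day 1 and 7.66 on day 2). The 24 general stress genes all rose, and 12 of 16 ER chaperone and folding genes rose. KAR2 rose by 0.93 ± 0.09 on the log2 scale (adjusted p = 2.22e-06; 0.73 on day 1 and 1.03 on day 2), HAC1 by 1.09 ± 0.11 (adjusted p = 1.76e-06; 0.89 and 1.20) and ERO1 by 1.62 ± 0.11 (adjusted p = 1.20e-07; 1.34 and 1.76). OPI1 rose by 0.30 ± 0.10 (adjusted p = 0.0128; 0.46 and 0.22).

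The general stress list had a median of 2.35 in Δcho2, 2.13 on day 1 and 2.51 on day 2 (camera adjusted p = 1.58e-08, adjusted p = 0.628 with an estimated correlation). HSP12, a small membrane-associated stress protein, rose 29.7-fold, GAC1 29.4-fold and DDR2 20.4-fold. Of 25 cytosolic and mitochondrial chaperone genes 22 rose and 1 fell, with HSP26 24.6-fold and SSA4 7.21-fold higher; the medians were 0.37 on day 1 and 0.72 on day 2 (camera adjusted p = 9.14e-04, adjusted p = 0.628 with an estimated correlation). Cell wall integrity genes rose in 19 of 23 cases and fell in 2, with PIR3, a cell wall protein, 36.3-fold and GSC2, a glucan synthase subunit, 13.8-fold higher (medians 0.73 and 0.93 by day; camera adjusted p = 1.76e-04, adjusted p = 0.628 with an estimated correlation). In vacuolar proteases and autophagy 14 of 17 rose and 1 fell, with ATG39 4.81-fold and ATG8 4.48-fold higher (medians 0.64 and 1.08 by day; camera adjusted p = 6.02e-04, adjusted p = 0.628 with an estimated correlation). In peroxisome and beta-oxidation 14 of 17 rose and 1 fell, with POT1, a peroxisomal thiolase, 30.0-fold and POX1, an acyl-CoA oxidase, 22.9-fold higher (medians 0.47 and 0.57 by day; camera adjusted p = 0.00127, adjusted p = 0.628 with an estimated correlation). With p adjusted over the list alone, 24 general stress, 22 chaperone, 19 cell wall, 15 vacuolar and 14 peroxisomal genes rose.

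Of 16 ER chaperone and folding genes 12 rose, 1 fell and 3 were not called in Δcho2, with a median of 0.73 (0.68 on day 1 and 0.76 on day 2), ERO1 3.08-fold and SIL1 2.90-fold higher (camera adjusted p = 0.00171, adjusted p = 0.628 with an estimated correlation). In ER translocation 13 of 21 genes fell and 1 rose, among them SSH1 (1.74-fold lower) and SRP14 (1.54-fold lower), with medians of -0.13 and -0.30 by day (camera adjusted p = 0.0151, adjusted p = 0.628 with an estimated correlation). Without CHO2, 11 of 18 phospholipid synthesis genes rose and 2 fell, and beside INO1 these were led by ITR1, an inositol transporter (2.34-fold higher), and INO4, an activator of INO1 (2.09-fold higher), with medians of 0.57 and 0.61 by day (camera adjusted p = 0.0405, adjusted p = 0.628 with an estimated correlation). Of 12 sporulation and meiosis genes 10 rose and 2 fell, with HOP1 7.28-fold and SPO11 5.12-fold higher and SPS4 5.26-fold lower (medians 0.98 and 1.29 by day; camera adjusted p = 0.0218, adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 12 ER chaperone, 11 phospholipid and 10 sporulation genes rose and 13 ER translocation genes fell.

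As after DTT, ribosome genes were lower in Δcho2. Of 132 ribosomal protein genes 130 fell and 2 were not called, with RPL9A 2.36-fold lower and medians of -0.64 and -0.85 by day (camera adjusted p = 4.36e-24, adjusted p = 0.628 with an estimated correlation). All 34 ribosome biogenesis genes fell (DBP2 2.35-fold; medians -0.55 and -0.82 by day) and all 10 histone genes fell (HTB2 2.74-fold; medians -0.60 and -0.80 by day), with camera adjusted p of 6.63e-09 and 1.30e-04 (adjusted p = 0.628 with an estimated correlation for both). Of 30 amino acid synthesis genes 22 fell and 4 rose, with LYS20 2.96-fold lower (medians -0.44 and -0.39 by day; camera adjusted p = 1.61e-04, adjusted p = 0.628 with an estimated correlation). The counts that fell were 130 ribosomal protein, 34 biogenesis, 10 histone and 22 amino acid synthesis genes when adjusted over the list alone. The other high genes by the naming rule were ADH7 (41.4-fold), SHH3 (37.0-fold) and MF(ALPHA)1, the alpha-factor gene (30.1-fold, well above background on 2 of 3 WT arrays). The lowest were INA1 (6.59-fold), YOL014W (5.38-fold), SPS4, YNL018C (4.52-fold), MOR1 (3.82-fold) and YLR112W (3.33-fold), of which YNL018C and MOR1 were well above background on 1 of 3 Δcho2 arrays. In all, limma called 4624 of 6115 genes, 2440 higher and 2184 lower, and 793 differed at least 2-fold (662 higher and 131 lower). The share higher was 52.8%, 39.8% under quantile normalisation and 40.6% with median centring, so the balance turned with the scaling. The 3 Δcho2 arrays all lay on the same side of the WT arrays for 69.1% of genes, against 10% by chance if arrays were exchangeable, a rough guide only where both groups span the days.

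In Δopi3, which lacks the enzyme of the last methylation steps, 13 of 16 ER chaperone and folding genes and all 24 general stress genes rose. KAR2 rose by 1.48 ± 0.09 on the log2 scale (adjusted p = 4.54e-08; 1.22 on day 1 and 1.61 on day 2). HAC1 rose by 1.52 ± 0.11 (adjusted p = 1.07e-07; 1.37 and 1.59) and ERO1 by 2.60 ± 0.11 (adjusted p = 2.95e-09; 2.48 and 2.66). INO1 rose 55.2-fold (log2 5.79 ± 0.51, adjusted p = 6.80e-07; 5.78 and 5.79). OPI1 was not called (0.07 ± 0.10, adjusted p = 0.535).

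Of 16 ER chaperone and folding genes 13 rose and 3 were not called in Δopi3, with a median of 1.46 (1.28 on day 1 and 1.51 on day 2), SIL1 6.76-fold and EUG1 4.13-fold higher (camera adjusted p = 1.03e-05, adjusted p = 0.628 with an estimated correlation). In ER-associated degradation 14 of 18 rose and 2 fell, with DER1 4.56-fold and DFM1 3.05-fold higher (medians 0.45 and 0.50 by day; camera adjusted p = 0.00127, adjusted p = 0.628 with an estimated correlation). In transport between ER and Golgi 20 of 30 rose and 5 fell, with ERV29 2.85-fold and SEC24 2.02-fold higher (medians 0.28 on both days; camera adjusted p = 0.00385, adjusted p = 0.628 with an estimated correlation). All 24 general stress genes rose, with HSP12 27.9-fold, GAC1 19.2-fold and GPH1 13.9-fold higher and a median of 2.13 (1.61 on day 1 and 2.38 on day 2; camera adjusted p = 8.95e-08, adjusted p = 0.628 with an estimated correlation). Of 23 cell wall integrity genes 18 rose and 2 fell, with PIR3 34.4-fold and GSC2 12.9-fold higher (medians 0.92 and 1.01 by day; camera adjusted p = 1.97e-04, adjusted p = 0.628 with an estimated correlation). Vacuolar proteases and autophagy had 14 of 17 genes higher and 1 lower, with PRB1 3.89-fold and ATG8 3.57-fold higher (medians 0.82 and 1.02 by day; camera adjusted p = 9.90e-04, adjusted p = 0.628 with an estimated correlation). Of 12 sporulation and meiosis genes 9 rose and 3 fell, with HOP1 18.6-fold higher (medians 0.99 and 0.79 by day; camera adjusted p = 0.0494, adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone, 13 ER chaperone, 14 ER-associated degradation, 20 transport, 24 general stress, 18 cell wall, 14 vacuolar and 9 sporulation genes rose.

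Ribosome genes were lower in Δopi3 too. Of 132 ribosomal protein genes 130 fell and 2 were not called, with RPS29A 2.11-fold lower and medians of -0.64 and -0.72 by day (camera adjusted p = 8.44e-19, adjusted p = 0.628 with an estimated correlation). All 34 ribosome biogenesis genes fell (DBP2 2.64-fold; medians -0.77 and -0.87 by day) and all 10 histone genes fell (HTB2 2.97-fold; medians -0.55 and -0.72 by day), with camera adjusted p of 2.21e-08 and 5.03e-04 (adjusted p = 0.628 with an estimated correlation for both). Of 27 ergosterol synthesis genes 17 fell and 2 rose, among them ERG5 (1.95-fold lower) and HMG1 (1.80-fold lower), with medians of -0.33 and -0.24 by day (camera adjusted p = 0.0145, adjusted p = 0.628 with an estimated correlation). Of 30 amino acid synthesis genes 22 fell and 3 rose, with ARG3 3.11-fold lower (medians -0.43 and -0.39 by day; camera adjusted p = 0.00108, adjusted p = 0.628 with an estimated correlation). Of 32 respiratory chain genes 21 fell and 4 rose, with CYC1 3.25-fold lower (medians -0.45 and -0.21 by day; camera adjusted p = 0.0404, adjusted p = 0.797 with an estimated correlation). Of 7 a-cell markers 6 fell and 1 was not called, with MFA2 2.07-fold and STE2 2.06-fold lower (medians -0.92 and -0.85 by day; camera adjusted p = 0.00490, adjusted p = 0.628 with an estimated correlation). Of 5 alpha-cell markers 3 rose and 2 fell, a list that did not pass camera (adjusted p = 0.747), with STE3 4.46-fold higher. Adjusted over the list alone, 130 ribosomal protein, 34 biogenesis, 10 histone, 17 ergosterol, 22 amino acid, 21 respiratory and 6 a-cell genes fell.

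Beside INO1, PIR3 and HSP12, the highest in Δopi3 by the naming rule were SHH3 (43.2-fold), ULI1 (33.8-fold) and YLR349W (30.4-fold). The lowest were INA1 (7.09-fold), BSC1 (7.03-fold, well above background on 1 of 3 Δopi3 arrays), SPL2 (6.12-fold; log2 -2.61, from -3.22 to -2.16 and still called with any 1 WT array left out), the iron oxidase gene FET3 (5.84-fold; log2 -0.82 on day 1 and -3.41 on day 2), the nicotinamide riboside transporter gene NRT1 (5.50-fold) and YOL014W (5.43-fold). In all, limma called 4727 of 6115 genes, 2319 higher and 2408 lower, and 808 differed at least 2-fold (632 higher and 176 lower). The share higher was 49.1% and fell to 40.6% under quantile normalisation. The 3 Δopi3 arrays all lay on the same side of the WT arrays for 68.4% of genes, against 10% by chance. The list calls of respiratory chain, sporulation, ergosterol and amino acid synthesis in Δopi3, and those of ER translocation, phospholipid synthesis and sporulation in Δcho2, ended under at least 1 alternative setting.

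**Figure D2:**
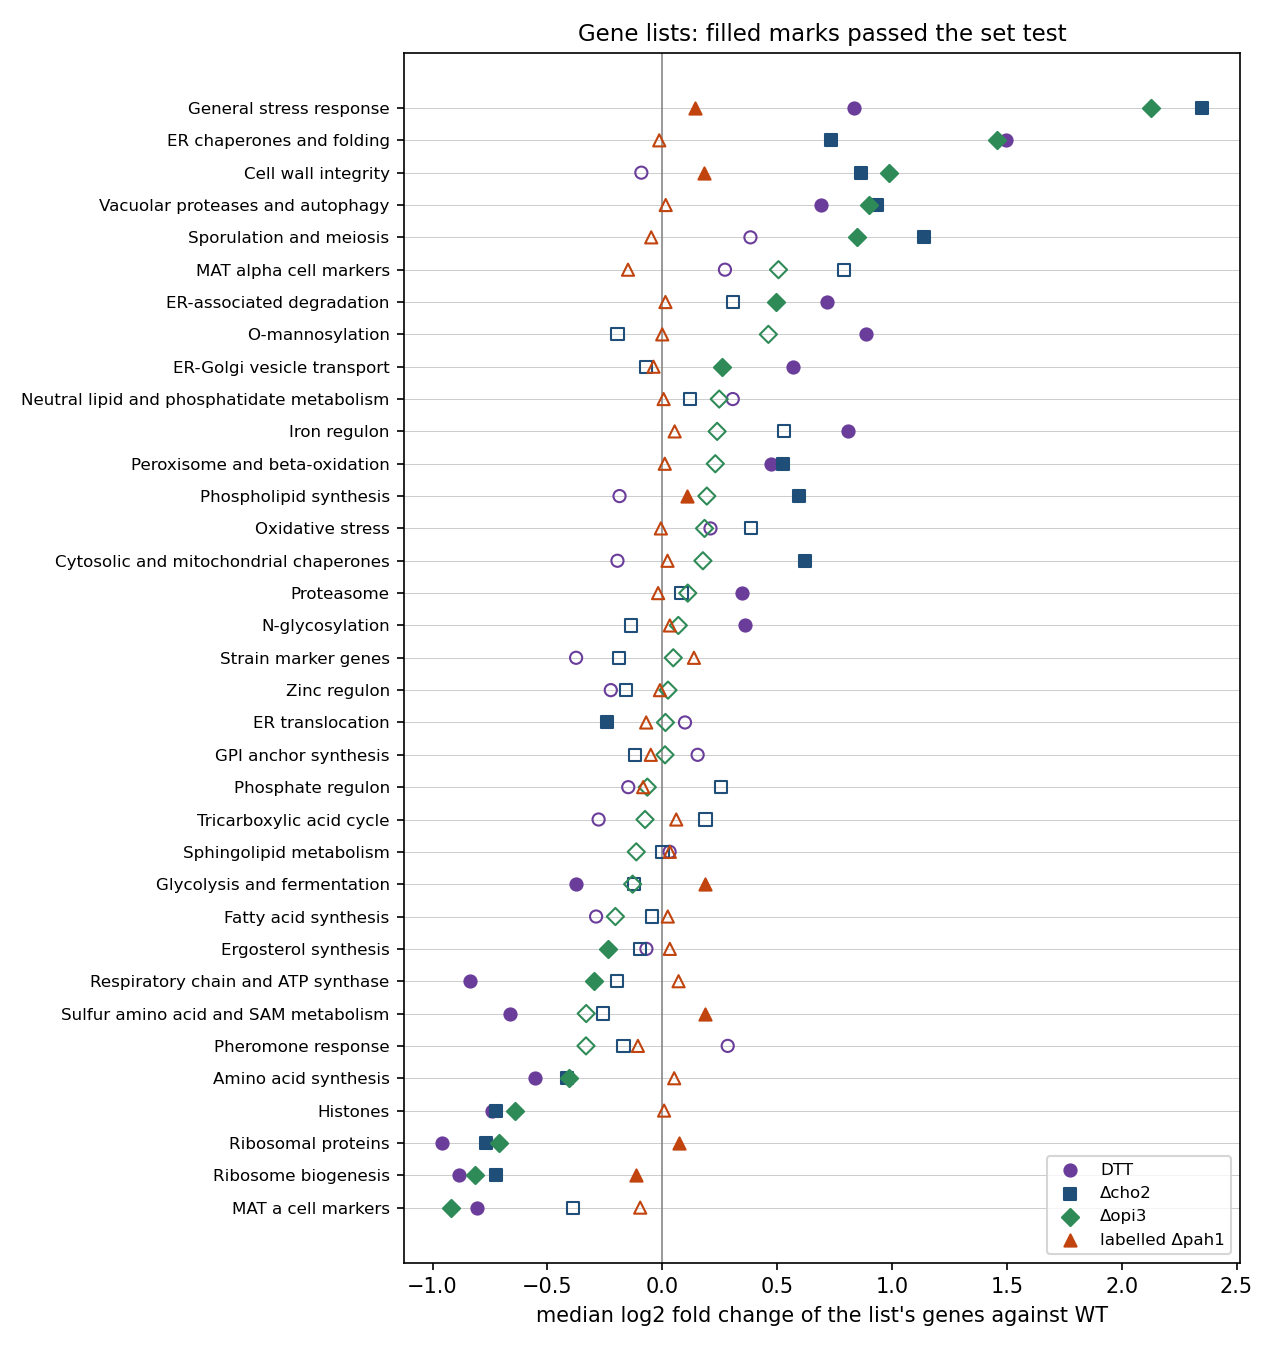
Median log2 fold change against WT of the genes of each of the 35 gene lists, for DTT, Δcho2, Δopi3 and the arrays labelled Δpah1, with filled marks where camera passed its threshold. General stress genes lay highest in Δcho2 (2.35) and Δopi3 (2.13), ER chaperones lay at 1.498 after DTT and 1.46 in Δopi3, and ribosomal proteins lay between -0.96 and -0.71 in the 3; the DTT value of glycolysis (-0.37) turned to 0.095 and the ribosomal protein value of the arrays labelled Δpah1 (0.07) turned to -0.03 under quantile normalisation.

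On the arrays labelled Δpah1, which pool unlike arrays, no change was called in the ER folding markers or INO1. KAR2 (-0.11 ± 0.09, adjusted p = 0.511; -0.04 on day 1 and -0.14 on day 2), HAC1 (0.36 ± 0.11, adjusted p = 0.0658; 0.51 and 0.29) and ERO1 (0.12 ± 0.11, adjusted p = 0.565; 0.31 and 0.02) were not called. INO1 was not called either (1.37 ± 0.51, adjusted p = 0.126), at 3.24 on day 1 and 0.44 on day 2. OPI1 rose by 0.44 ± 0.10 (adjusted p = 0.0278; 0.69 and 0.31). Lower by the naming rule were the phosphate transporter gene PHO84 (log2 -2.10 ± 0.52, adjusted p = 0.0410; -2.09 and -2.11 by day), SPL2 (-1.66 ± 0.42, adjusted p = 0.0435), YIL082W (-1.24), LFT1 (-0.88), COB, the mitochondrial cytochrome b gene (-0.88 ± 0.08, adjusted p = 7.95e-04; -0.81 and -0.92 by day), and AI1 (-0.84), read from the mitochondrial genome too. Both PHO84 and SPL2 varied between WT cultures of the same slide (-2.91 and -0.65 relative to the 75th percentile for PHO84, -6.20 and -4.20 for SPL2), and both calls ended without WT replicate 1 (-1.795 and -1.46) or WT replicate 3 (-1.62 and -1.20) and without replicate 2 (-1.97 and -1.74) or 3 (-1.99 and -1.565) of the arrays labelled Δpah1. The SPL2 call also ended without replicate 1 of these arrays (-1.67). Higher were YIR043C (log2 0.81), YCR013C (0.76), and REC114, YCL042W, YGR273C and YHL041W. The last 4 genes were well above background on 1 array labelled Δpah1 and on no WT array, so no fold is given for them.

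Of the 35 lists 7 passed camera on these arrays, each with a median no larger than 0.19 in size, and each of the 7 calls ended or turned under at least 1 alternative (the cell wall list had a median of 0.005 without replicate 1 of its group). Glycolysis and fermentation had 4 of 17 genes higher, with TDH1 1.33-fold and TDH2 1.26-fold higher and medians of 0.02 and 0.27 by day (camera adjusted p = 3.57e-06, adjusted p = 0.628 with an estimated correlation). Ribosomal proteins had 5 of 132 genes higher, with RPS6B 1.39-fold higher, and a median of 0.07 that was -0.03 on day 1 and 0.12 on day 2 and turned to -0.03 under quantile normalisation (camera adjusted p = 2.16e-04, adjusted p = 0.756 with an estimated correlation). Ribosome biogenesis had 1 of 34 genes lower, RPA190 (1.20-fold), with medians of -0.21 and -0.12 by day (camera adjusted p = 0.00226, adjusted p = 0.756 with an estimated correlation). In phospholipid synthesis OPI1 was the 1 gene called of 19 (medians 0.15 and 0.10 by day; camera adjusted p = 0.0326, adjusted p = 0.628 with an estimated correlation). In general stress SPI1 was the 1 gene called of 24, 1.28-fold higher (medians 0.21 and 0.12 by day; camera adjusted p = 0.0334, adjusted p = 0.778 with an estimated correlation). No single gene of the 28 in sulfur amino acid metabolism (medians 0.12 and 0.25 by day; camera adjusted p = 7.71e-04, adjusted p = 0.713 with an estimated correlation) was called by limma. The same held for the 23 cell wall integrity genes, with medians of 0.42 and 0.06 by day (camera adjusted p = 0.0114, adjusted p = 0.729 with an estimated correlation). With p adjusted over the list alone, 6 glycolysis, 3 ribosomal protein, 1 phospholipid and 1 general stress gene rose, and 0 genes of the biogenesis, sulfur and cell wall lists were called.

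In all, limma called 373 of 6115 genes on the arrays labelled Δpah1, 160 higher and 213 lower, 5 of them at least 2-fold, and 1518 had an unadjusted p under 0.05. The share higher was 42.9% and 53.6% with median centring, so the balance turned with the scaling. The 3 arrays lay on the same side of the WT arrays for 15.2% of genes, against 10% by chance for exchangeable arrays, which these are not, as both groups span the days. The count was 778 from day 2 alone, where strain and slide coincide, 5 without the day term, 97 with the slide as a random block, 34 with the replicate number as a block, 27 without WT replicate 2, 84 without WT replicate 3, 70 without replicate 2 of the arrays labelled Δpah1, and 222, 176 and 184 without DTT replicates 1, 2 and 3. Without the pair of arrays with PAH1 at the WT level the count was 1012, of which 189 were among the 373, with the lone array left assumed to vary like the other groups.

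The deletion strains were also compared directly, since comparisons with WT share the WT arrays. Gene lists were not tested in the direct contrasts. Between Δopi3 and Δcho2, KAR2, HAC1 and ERO1 were higher in Δopi3 and INO1 was lower. KAR2 was higher by 0.55 ± 0.09 on the log2 scale (adjusted p = 7.04e-04; 0.49 on day 1 and 0.58 on day 2), HAC1 by 0.42 ± 0.11 (adjusted p = 0.00839; 0.48 and 0.40) and ERO1 by 0.98 ± 0.11 (adjusted p = 4.71e-05; 1.14 and 0.90). INO1 fell by 1.71 ± 0.51 on the log2 scale (adjusted p = 0.0202, with -1.40 and -1.87 by day). With the slide as a fixed or random block the INO1 difference was -0.57 or -0.92 and no longer called. It was not called either without Δcho2 replicate 2 (-1.53), Δcho2 replicate 3 (-1.52) or Δopi3 replicate 1 (-1.45). On single arrays INO1 stood at 3.48 to 3.85 in Δcho2 and 1.88 to 2.08 in Δopi3, relative to the 75th percentile. The slide of Δopi3 replicates 2 and 3 held, beside them, only replicates 2 and 3 of the arrays labelled Δpah1. Higher in Δopi3 were YJL152W (10.8-fold; well above background on 1 of 3 Δcho2 arrays), ULI1 (7.20-fold), YOL037C (5.57-fold) and YGR259C (4.88-fold). Lower were MF(ALPHA)1 (17.0-fold), ADH7 (11.2-fold), NCA3 (8.87-fold) and PDC6 (6.28-fold). OPI1 was not called (-0.23 ± 0.10, adjusted p = 0.0738), nor was PAH1 (0.13, adjusted p = 0.861). In all, 2322 genes were called, 936 higher and 1386 lower, and 148 differed at least 2-fold; the share higher was 40.3%, 53.9% under quantile normalisation and 57.1% with median centring, so the balance turned with the scaling, and 1357 genes were called without the day term.

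Between Δcho2 and DTT-treated WT, KAR2, HAC1 and ERO1 were lower in Δcho2 and INO1 was higher. KAR2 fell by 0.56 ± 0.10 on the log2 scale (adjusted p = 2.33e-04), HAC1 by 0.52 ± 0.11 (adjusted p = 0.00108) and ERO1 by 1.01 ± 0.12 (adjusted p = 7.93e-06). INO1 was 21.2-fold higher in Δcho2 (adjusted p = 1.08e-05), and OPI1 was 1.46-fold higher. Highest were PIR3 (111-fold), GAC1 (at least 57.5-fold), MF(ALPHA)1 (at least 21.8-fold) and GPH1 (56.5-fold); GAC1 and MF(ALPHA)1 were not well above background on any DTT array. Lowest were YJL152W (21.9-fold; well above background on 1 of 3 Δcho2 arrays), YJR079W (8.11-fold), NFG1 (7.55-fold) and ARO10 (7.03-fold). The contrast called 4404 genes, 2150 higher and 2254 lower in Δcho2, and 693 of them differed at least 2-fold (495 higher and 198 lower). The share higher of all called genes was 48.8% and 41.6% under quantile normalisation.

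Between Δopi3 and DTT-treated WT, no difference was detected in KAR2 (-0.01 ± 0.10, adjusted p = 0.969), HAC1 (-0.10 ± 0.11, adjusted p = 0.456) or ERO1 (-0.04 ± 0.12, adjusted p = 0.806), which does not show that they are equal. INO1 was 6.48-fold higher in Δopi3 (adjusted p = 6.75e-04), and OPI1 was higher by 0.32 on the log2 scale. Highest were PIR3 (log2 6.71), GAC1 (at least 37.6-fold), GPH1 (39.3-fold) and YLR162W (21.2-fold). Lowest were NFG1 (21.6-fold), NCA3 (20.2-fold), FET3 (8.53-fold) and ARO10 (7.55-fold). The FET3 fold averages unlike Δopi3 arrays, as the log2 difference of Δopi3 from WT was -0.82 on day 1 and -3.41 on day 2. The contrast called 4174 genes, 1837 higher and 2337 lower in Δopi3, and 502 of them differed at least 2-fold (370 higher and 132 lower). The share higher of all called genes was 44.0% and 51.2% with median centring, so the balance turned with the scaling. Against the day 2 arrays of Δopi3 alone the differences from DTT were 0.08 in KAR2, -0.05 in HAC1 and 0.00 in ERO1, and against those of Δcho2 alone they were -0.51, -0.44 and -0.90.

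**Figure D3:**
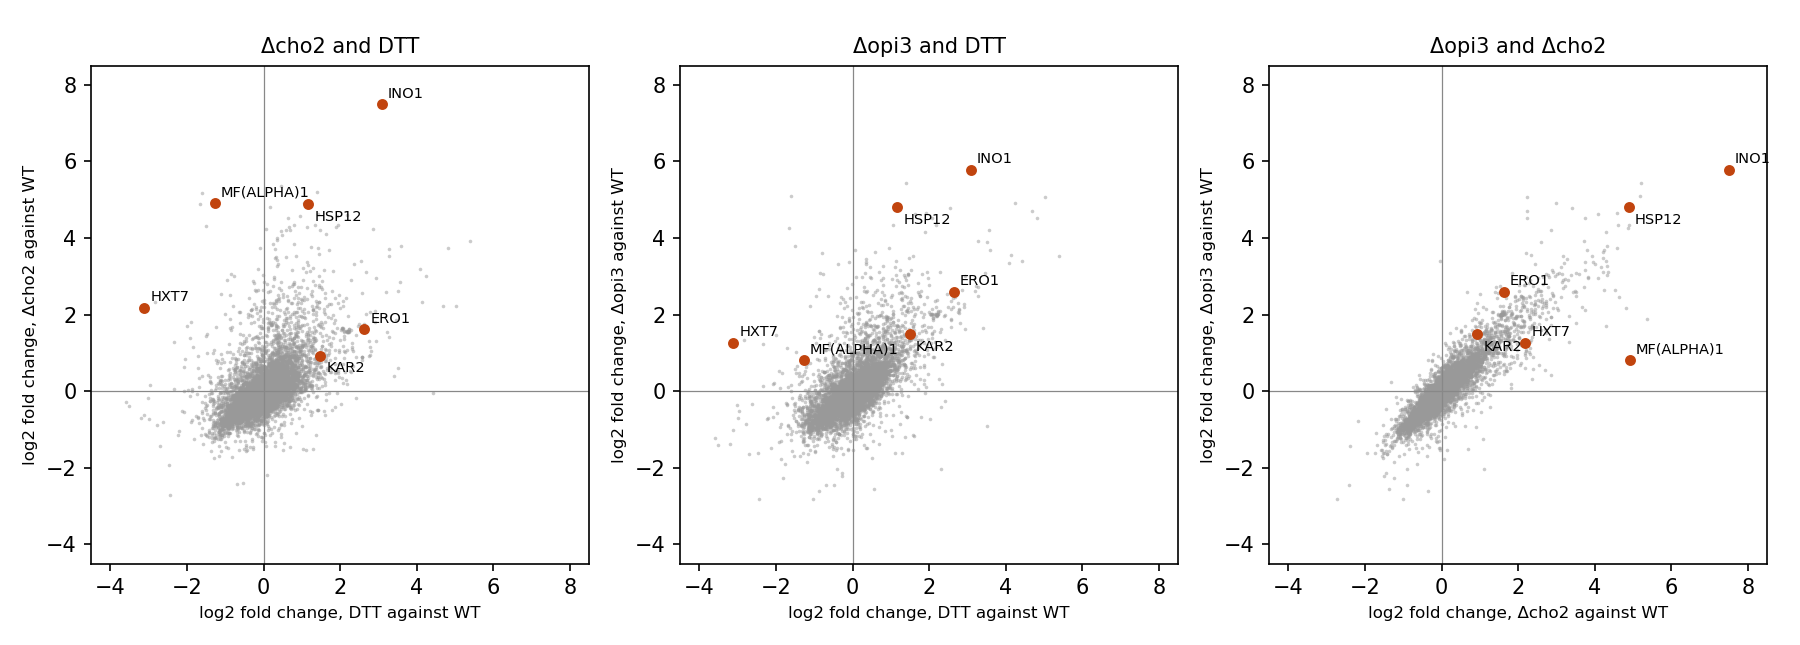
Log2 fold change against WT of each tested gene (CHO2, OPI3 and PAH1 left out), for Δcho2 against DTT, Δopi3 against DTT and Δopi3 against Δcho2, with 6 genes marked in colour. The correlation across genes was 0.525, 0.643 and 0.879; HXT7 was lower after DTT and higher in both deletion strains, and INO1 was higher in all 3.

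The arrays labelled Δpah1 differed from Δcho2 in 4617 genes (775 at least 2-fold), from Δopi3 in 4660 (736) and from DTT-treated WT in 4702 (825). INO1 was 69.8-fold lower on them than in Δcho2, 21.3-fold lower than in Δopi3 and 3.29-fold lower than after DTT (adjusted p = 0.0101), and the last difference was no longer called with the slide as a fixed block (log2 -0.33) or a random block (-0.74), from only the groups compared (-1.49) and without replicate 2 (-1.325) or 3 (-1.22) of these arrays, and it turned to 0.50 without the arrays with PAH1 at the WT level. By day the INO1 difference was -3.945 and -7.22 from Δcho2 and -2.545 and -5.35 from Δopi3, so the pooled folds average unlike arrays. KAR2 was lower by 2.06-fold, 3.01-fold and 3.02-fold against Δcho2, Δopi3 and DTT, HAC1 by 1.66-fold, 2.23-fold and 2.38-fold, and ERO1 by 2.84-fold, 5.61-fold and 5.74-fold. Higher on them were INA1 (6.06-fold) and SPS4 (5.37-fold) against Δcho2, INA1 (6.52-fold) and ATO3 (5.40-fold) against Δopi3, and HPF1 (13.6-fold) and CSS1 (10.9-fold) against DTT. Lower were ADH7 (44.5-fold) and SHH3 (30.5-fold) against Δcho2, SHH3 (35.5-fold) and DIA3 (31.3-fold) against Δopi3, and ULI1 (33.4-fold) and TIS11 (26.6-fold) against DTT. For 72.8% of genes the 3 Δcho2 arrays lay on the same side of the 3 DTT arrays, for 68.3% those of Δopi3, and for 35.4% the Δopi3 arrays lay on the same side of the Δcho2 arrays, against 10% by chance.

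Δcho2 and Δopi3 changed largely together. Of the genes called in both comparisons with WT, 2004 were higher in both, where independent lists would share 925, 1916 were lower in both (expected 860) and 86 went opposite ways. The correlation across genes, which are not independent replicates, was 0.879. Comparisons that share WT arrays correlate even without change (mean 0.498 over 50 simulations), so the covariance is the better guide: it was 0.580, against 0.00569 in the simulations, which called 0 genes in the same direction in both. With no shared WT arrays, day 1 of Δcho2 against day 2 of Δopi3 gave 0.852 and the reverse 0.845, while Δcho2 between the days gave 0.963 and Δopi3 0.950. DTT shared 1638 higher and 1383 lower genes with Δcho2 (expected 1029 and 762; 646 opposite) and 1701 higher and 1569 lower with Δopi3 (expected 978 and 840; 515 opposite), with correlations across genes of 0.525 and 0.643 and covariances of 0.314 and 0.373. Against DTT, day 1 of Δcho2 gave 0.528 and day 1 of Δopi3 0.657 with no shared WT array. All 3 changed 2756 genes in the same direction, 1452 higher and 1304 lower. The arrays labelled Δpah1 correlated at 0.187 between the days, and their day 1 array correlated at 0.378 with day 2 of Δcho2 and 0.379 with day 2 of Δopi3.

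**Figure D4:**
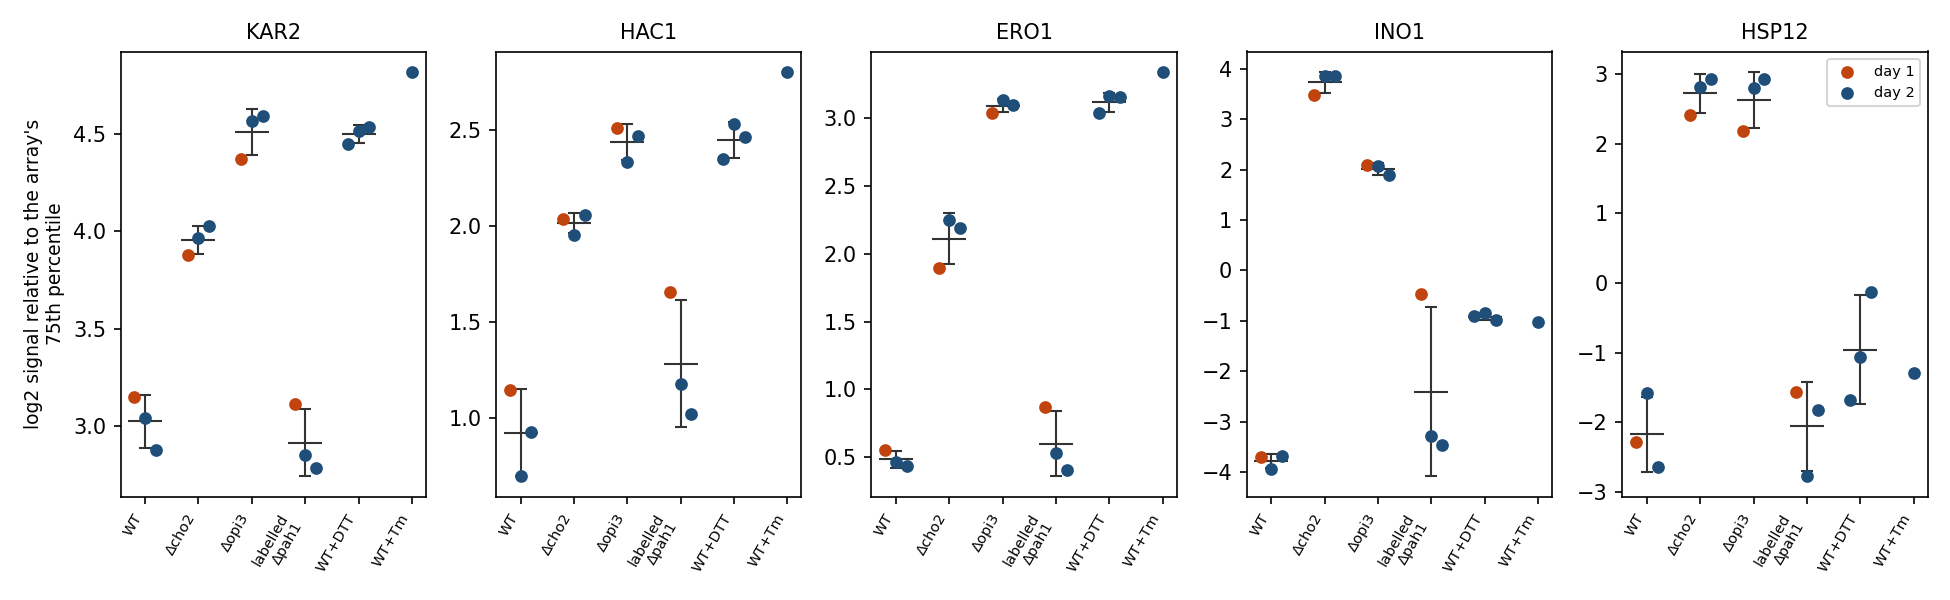
Log2 signal of KAR2, HAC1, ERO1, INO1 and HSP12 relative to the 75th percentile of each array, for each of the 16 arrays, with the mean and SD of groups of 3 and colours for the day. INO1 was 181-fold higher in Δcho2 and 55.2-fold higher in Δopi3 than in WT, and HSP12 was 29.7-fold and 27.9-fold higher.

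Tunicamycin, which blocks N-glycosylation, was applied to 1 culture, so its values carry no test. Against the mean of the 2 WT arrays of its slide, KAR2 was higher by 1.86 on the log2 scale, HAC1 by 2.00, ERO1 by 2.89 and INO1 by 2.78, while OPI1 differed by -0.41. The highest were YLR349W (5.22), ULI1 (4.98), YOL037C (4.43), YET2 (3.91), DOG1 (3.62) and GSC2 (3.51), and the lowest INA1 (-4.01), CSS1 (-3.71), HPF1 (-3.58), YER053C-A (-3.31), PHO3 (-3.24) and FET3 (-3.12). Of 5848 genes well above background on these arrays, 360 were at least 2-fold higher and 179 at least 2-fold lower, against 3 genes at least 2-fold apart between the 2 WT arrays. The correlation across genes with the DTT difference was 0.880, and 0.872 and 0.864 when each treatment was set against a different WT array. The median of the ER chaperone list was 1.63 (DTT 1.54 against the same WT arrays) and that of ribosome biogenesis -0.81 (DTT -0.89). The medians stood at percentiles 100 and 0 of 10000 random lists of like expression. List medians that stood apart between tunicamycin and DTT, differences that were not tested, included the iron regulon (-0.16 with tunicamycin, 0.77 with DTT; FET3 -3.12 and 0.33), the respiratory chain (-0.09 and -0.78) and ribosomal proteins (-0.42 and -0.98). The same held for cytosolic and mitochondrial chaperones (0.35 and -0.12) and cell wall integrity genes (0.32 and -0.05).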

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

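The comparisons of strain by day and the tests that weigh explanations were chosen only after the results were seen, whereas the splits of the arrays were planned. Day 1 holds 1 array per group, so the spread behind any comparison of days comes from day 2 alone, largely from arrays of the same slide, and the counts and values here are descriptive, with no valid test. In a fit with separate strain effects for each day (6 residual degrees of freedom), the difference from WT passed the threshold between the days for 9 of 6115 genes in Δcho2, 53 in Δopi3 and 760 on the arrays labelled Δpah1. For PAH1 on the arrays labelled Δpah1 the change between days was 3.018 (from -3.01 on day 1 to 0.01 on day 2). For INO1 on the same arrays it was -2.796 (from 3.24 to 0.44). For OPI3 in Δopi3 it was -3.181 (from -3.57 to -6.76).

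PAH1 at the WT level on arrays 2 and 3 labelled Δpah1 speaks against a deletion of the probed part of PAH1 in those cultures. An exchange with WT arrays of this series would leave an array of another group with low PAH1 signal, but the lowest of the other 13 stood at 93.34% of the WT mean. A difference between days in the probe would show in other groups, where it was at most 0.192 on the log2 scale against 2.83 on the arrays labelled Δpah1. RNA of cells with a working PAH1 gene is a candidate explanation. Over 157 genes changed at least 1.5-fold on day 1 (1 array per group) the change on day 2 was 0.104 of that on day 1, against 1.24 in Δcho2 and 1.03 in Δopi3. Genes picked for a large difference between single arrays tend to differ less on other arrays, most of all where true changes are small. Δcho2 and Δopi3, with 1354 and 1786 such genes, are thus an uneven yardstick, and the ratio alone cannot decide. Not all differences from WT were lost on day 2, as COB (-0.81 and -0.92 by day), COX1 (-0.86 and -0.73) and HIS3 (0.54 and 0.35) show, but these genes were picked for that and test nothing, and the 778 genes called on day 2 alone do not help, since strain and slide coincide there. A construct that leaves the probed part of PAH1 in place, and a strain that regained the gene, stay open as untested.

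General stress genes rose as a whole in Δcho2 and Δopi3. A difference between the days or slides would not raise them on each day, yet the lowest median within a day was 1.612 on the log2 scale. A shift to respiratory growth after glucose exhaustion would raise respiratory genes, whose highest median in these strains was -0.197, with 17 of 32 lower in Δcho2 and 21 in Δopi3. The rise of HXT6, HXT7 and POT1 goes with partial relief from glucose repression, which that median does not exclude. These genes were picked for their rise and test nothing. Of 16 HXT genes 11 rose and 1 fell in Δcho2, and 13 rose and 3 fell in Δopi3. HXT4 did not rise, at 0.17 in Δcho2 (limma adjusted p = 0.45) and -0.51 in Δopi3 (limma adjusted p = 0.0305). An effect of the missing methyltransferases, which may act through the membrane or through slower growth, stays open as untested.

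For each of the 10 contrasts, 1 of the 10 splits of its 6 arrays, the real one, gave as many called genes, and 10 splits are too few for a share under 0.05. Every other split mixes arrays of both groups under 1 name. A wide difference between the groups then becomes spread within them, and the count falls towards 0 by construction. The gaps between the counts below therefore add no support. The real and the highest other counts against WT were 4713 and 0 for DTT, 4624 and 0 for Δcho2, 4727 and 0 for Δopi3, and 373 and 45 for the arrays labelled Δpah1. For Δopi3 against Δcho2 they were 2322 and 0, and against DTT they were 4404 and 0 for Δcho2, 4174 and 0 for Δopi3 and 4702 and 0 for the arrays labelled Δpah1. These arrays gave 4617 and 1 against Δcho2 and 4660 and 0 against Δopi3.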

How the results depend on the processing

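The fit without the doubted pair of arrays labelled Δpah1 and the procedure in the authors' note were chosen after seeing the data; the other alternatives were planned. The counts of called genes for DTT, Δcho2 and Δopi3 against WT stayed within 1.5 times their reported value under each alternative except a fold of at least 1.5 and the authors' procedure, which changes the filter, the test and the fold together. Like counts do not mean the same genes. With quantile normalisation 4021 of 4713, 3951 of 4624 and 4153 of 4727 genes kept their call and direction, and 22, 140 and 56 were called the opposite way. The count for the arrays labelled Δpah1 (373) was 144 with quantile normalisation, 5 without the day term, 97 with the slide as a random block, 778 from day 2 alone, 34 with the replicate block, 4 from only the 2 groups compared and 1012 without the pair with PAH1 at the WT level. Leaving out single arrays gave 27 (WT replicate 2) to 521 (Δcho2 replicate 1), with 84 without WT replicate 3, 70 without replicate 2 of its own group and 222, 176 and 184 without DTT replicates 1, 2 and 3. The cause was not tested. Of the 373 genes, 278 were also called from day 2 alone, 104 with the slide as a fixed block (527 called) and 67 with it as a random block, 189 without the doubted pair and 27 without WT replicate 2. Δopi3 against Δcho2 fell from 2322 to 1357 genes without the day term.

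With a fold of at least 1.5 the counts against WT were 2096 (DTT), 1904 (Δcho2), 2013 (Δopi3) and 42 (labelled Δpah1), 466 for Δopi3 against Δcho2, 1855 and 1913 for the arrays labelled Δpah1 against Δcho2 and Δopi3, 1635, 1330 and 2138 for Δcho2, Δopi3 and the arrays labelled Δpah1 against DTT, and 903 genes changed alike in DTT, Δcho2 and Δopi3 (2756 as reported). The authors' procedure, which kept 5173 genes, of which 4937 passed a first test across groups, and asks for 2-fold, gave in the same order 495, 553, 599, 1, 60, 513, 530, 397, 273, 514 and 175. Of the 52 list calls, 0 were left with an estimated correlation and fry made 90. The reversals that follow are those among the list results and the values of named genes only. Reversed were MF(ALPHA)2 after DTT with normexp correction (-0.140); with quantile normalisation glycolysis after DTT (0.095), ribosomal proteins on the arrays labelled Δpah1 (-0.026), AGA2 in Δcho2 (-0.305) and PFK1 in Δopi3 (0.069); general stress on the arrays labelled Δpah1 with the slide as a fixed block, whose median was 0.063 while camera turned; and, without the doubted pair, ribosomal proteins on the array left (-0.082) and INO1 between it and DTT (0.50). The cause was not tested. Leaving aside the estimated correlation and fry, 20 of 140 list results lost and 26 gained a call under at least 1 alternative, and of 608 values of named genes 127 lost and 19 gained one. The probe of highest signal was not run, as each gene has 1 probe. The normexp correction used the median spot signal, in place of the planned mean. Signal over background limits few genes, since at least 91.1% were well above background on each array. The limit was not alike across groups, though. The dimmest detected signal was 7.24 to 17.5 units on WT arrays and 27.5 to 44.9 on the day 2 arrays of the other modelled groups. Differences of dim genes from WT are less sure for that reason. SPL2 on Δopi3 replicates 2 and 3 (30.39 and 49.95 units), for example, lay near the limit of its arrays (27.45 and 39.93).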

Other observations

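The gene families in this part and the tests of mating type were chosen only after the results were seen, while the values of HXT7 after DTT and of COB come from the planned fit and naming rule. Of the hexose transporter genes, HXT6 and HXT7 moved opposite ways after DTT and in Δcho2 and Δopi3. Probe sequences were not analysed, so HXT6 and HXT7 are not shown to be separate measurements. HXT7 and HXT6, high-affinity transporters, were 8.64-fold and 7.16-fold lower after DTT, 4.53-fold and 5.03-fold higher in Δcho2 and 2.41-fold and 2.51-fold higher in Δopi3, and in the direct contrast HXT7 was 39.2-fold higher in Δcho2 than after DTT (adjusted p = 5.48e-10). HXT5 rose in all 3, 7.19-fold, 19.0-fold and 6.22-fold. Of 16 HXT genes 10 rose and 5 fell after DTT, 11 rose and 1 fell in Δcho2 and 13 rose and 3 fell in Δopi3 (camera adjusted p = 0.688, 0.00944 and 0.00944 over 12 family tests, adjusted p = 0.846, 0.267 and 0.267 with an estimated correlation).

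All 24 seripauperin (PAU) genes rose after DTT, in Δcho2 and in Δopi3, with medians of 2.16, 1.57 and 2.00 (camera adjusted p = 3.50e-11, 6.31e-11 and 3.74e-12, adjusted p = 0.267 with an estimated correlation for each). These genes are near-identical copies, and their probes cannot be taken to measure them separately. On the arrays labelled Δpah1, 9 of 18 mitochondrially encoded genes fell and 0 rose, with a median of -0.41 (-0.46 under quantile normalisation; camera adjusted p = 4.55e-07, adjusted p = 0.0821 with an estimated correlation). COB, COX1 and COX3, subunits of the respiratory chain, were 1.84-fold, 1.71-fold and 1.33-fold lower. COB and COX1 were lower in Δopi3 too, 1.62-fold and 1.51-fold (adjusted p = 5.69e-06 and 4.45e-05). Of the 18 genes 3 rose and 5 fell in Δopi3, 5 rose and 2 fell in Δcho2 and 3 rose and 5 fell after DTT, and camera passed in none of the 3 (adjusted p = 0.840, 0.840 and 0.676). Their medians were -0.049, 0.155 and -0.046 in that order, but -0.370, -0.261 and -0.278 under quantile normalisation. How far the arrays labelled Δpah1 stand apart in these genes thus depends on the normalisation.

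The labels give mating type alpha, yet all 7 a-cell markers, among them STE2 (9034 to 9857 units on the WT arrays) and STE6 (16507 to 20191 units), were well above background on each of the 16 arrays. Of 5 alpha-cell markers, STE3, SAG1 and AFB1 were well above background on each array, MF(ALPHA)1 on 9 and MF(ALPHA)2 on 5. Cells of mating type a in place of alpha are a candidate explanation: MF(ALPHA)1, abundant in alpha cells, reached at most 3.935 times the dimmest detected signal on a WT array. This ratio was taken on the WT arrays alone. MF(ALPHA)1 stood at 17.3 to 28.5 units there and at 32.32 to 56.01 in Δopi3. It stood at 14.23 to 32.87 units on the arrays labelled Δpah1 and at 8.339 to 14.46 after DTT. On the tunicamycin array it was not well above background. The Δcho2 arrays were the exception, with MF(ALPHA)1 at 587 to 829 units. STE3 was 4.70-fold and 4.46-fold higher in Δcho2 and Δopi3. A mixture of cells of both mating types cannot be told apart from cells of mating type a. The share of alpha cells is not known. On every WT array 2 of 5 alpha-cell markers (SAG1 and AFB1) lay above 16 times the dimmest detected signal. No biological explanation was tested.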
